A study of Mus musculus with 8 samples.

How the data were processed

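RNA from the duodenum of 8 female BALB/c mice was measured on 8 arrays, 1 array per mouse. BALB/c is an inbred laboratory strain. The labels place 4 wild-type mice on a control diet in 1 group and 4 mice heterozygous for Mthfr on a low folate diet in the other, and describe the samples of a group as biological replicates. Per the labels' protocols, total RNA was turned into biotin-labelled single-stranded DNA with a whole-transcript labelling assay and hybridised in 1 colour.

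The deposited table holds 1 value on the log2 scale for each of 35556 probe sets on each array, made by the authors before deposit. The scale was read from the values, which run from 3.20 to 14.8, the range of the binary logarithm of a scanner signal. How the authors corrected the background, normalized the arrays and summarized probes into probe sets is not given in the sources used here. The arrays' sorted values differed from their mean by at most 0.078, so the arrays had been brought to 1 common distribution before deposit. Array medians lay between 7.63 and 7.69, and the correlation between 2 arrays over all probe sets lay between 0.988 and 0.996. Differences between groups are therefore relative to the other genes on the arrays, and a shift common to most genes would have been removed. The number of arrays limits the precision of each value.

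Probe sets were named through the platform annotation supplied with the data, which listed 23410 of the probe sets. Of these, 21789 carried 1 gene and 1621 carried several, and the latter were not named. No gene was listed for 12146 probe sets. Symbols were brought up to date through gene identifiers in a RefSeq gene table of the assembly GRCm38.p6, to which 21698 of the 21789 probe sets matched. That table was used only for names, chromosomes and the positions of genes, from which their order and their distance to Mthfr were taken. For a gene with several probe sets the one with the highest mean over the 8 arrays was used, which left 19938 genes. Genes whose mean lay below the 25th percentile (a log2 signal of 6.81) were left out, and 14953 were tested. Of the genes named by the rule, 7 had more than 1 probe set, and all probe sets of a gene differed in the same direction between groups. The sizes were 0.18 and 0.056 for Tk1, 0.20 and 0.35 for Gstm3, and -0.28 and -0.41 for Dnaja1. No probe set carried the name of Mthfr alone, so the level of Mthfr is not analysed here, nor are Cdkn1a, Dhfr, Hmgcr, Ldlr, Msh2 and Mlh1.

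The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 14953 genes and a threshold of 0.05. Differences are given as low folate heterozygotes minus controls on the log2 scale, with the standard error (SE) from the fit, and group levels as mean ± SD over 4 arrays. Because diet and genotype differed together, the contrast is of both at once. The groups, tests, gene lists, named genes and most of the alternatives were fixed before the data were examined. The text names Mthfr where measured and, in each direction, up to 12 genes past the threshold with groups that did not overlap, by size of change. Places left over were filled by unadjusted p, and predicted genes, olfactory and vomeronasal receptors and antigen receptor segments were passed over in this part of the rule but counted. It also names up to 4 members, by unadjusted p, of each gene list past its threshold and of 6 lists on folate, nucleotides, p53, cell division, Wnt and DNA methylation. Genes outside this rule are said to have been chosen after their values were seen.

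In all, 46 lists of pathways, cell types and technical signs were fixed, with 925 symbols, of which 830 matched a probe set. The 44 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 44 lists. Camera with an estimated correlation, fry and an exact permutation test of each list's mean standardized value over the 70 arrangements of the arrays were run as alternatives. A permutation of 4 against 4 arrays cannot give a p below 0.0286, so that last test cannot pass after adjustment over 44 lists. Fry and the permutation test use only a list's own genes. Unlike camera, they do not ask whether a list differs more than other genes do. Principal components were taken from the centred values of the tested genes. Genes near Mthfr were compared with all others by Fisher's exact test.

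Both groups carry the replicate numbers 1 to 4 in the labels, and nothing in the labels says what a number marks. Same-numbered arrays deviated together from their group means, with correlations of 0.28, 0.26, 0.48 and 0.15 for the 4 pairs, each above the bound of 0.1 set for pairing. Correlations between arrays of different number in the 2 groups ran from -0.37 to 0.22, and 6 of the 8 arrays correlated best with their own number. Without the pancreatic gene list the 4 correlations were 0.35, 0.08, 0.23 and 0.10. The pairing therefore comes from the data, not from the labels, and the fit with the replicate number as a block is given beside results that it changes. With the block, 2 genes passed the threshold in place of 4.

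Before use, the gene test was run on simulated data in 20 runs, with 200 genes changed by known amounts. The data had the means of these 14953 genes and independent normal noise with limma's moderated variances. It called 88.7% of genes changed by 0.5 on the log2 scale, 98.8% of those changed by 1 and 99.4% of those changed by 2, and 4.8% of its calls were unchanged genes. These shares hold for that noise and number of changed genes and are not the power of the real comparison. There, Plscr2 with a difference of 1.06 did not pass (limma adjusted p = 0.220). Camera with the preset correlation called 0.15 of 44 lists on average where genes were independent and nothing differed. Where the members of each list were made to covary and nothing differed, it called 22.1 of the 44, against 0.05 with an estimated correlation. The shared variation was as large as each gene's own in every list. In the real data the estimated correlation of the lists called ran from 0.075 for iron absorption to 0.908 for smooth muscle. The count of 22.1 is therefore not a rate of false calls for these data. Each call with the preset correlation is therefore given with the p from an estimated correlation.

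The alternatives were no filter or a filter at the 50th percentile, quantile normalization or median centring of the deposited values, every probe set tested on its own, and a moderated test with trend and robust variance. An ordinary t statistic, array weights, a pseudocount of 16 on the linear scale, the replicate block, other thresholds, windows of 5 and 20 Mb around Mthfr and leaving out each of the 8 arrays were also run. An alternative with the level of the pancreatic list as a covariate, one without both arrays numbered 4, and an exact test of the first component within numbered pairs were added after seeing the data. Each group comparison across many genes was also repeated for all 35 splits of the 8 arrays into 4 and 4. Figures were drawn with matplotlib 3.10.9.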

Results

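The series measured RNA from normal duodenum, the first part of the small intestine, of 8 female BALB/c mice. Mthfr encodes methylenetetrahydrofolate reductase, the enzyme that makes the methyl form of folate used to turn homocysteine into methionine. The control group held 4 wild-type mice given a diet with 2 mg folate per kg. The low folate group held 4 mice heterozygous for Mthfr given a diet with 0.3 mg folate per kg. The diets were eaten for 1 year after weaning and held 1% succinylsulfathiazole, a drug that keeps gut bacteria from making folate. Intestines had been inspected for tumours, and normal tissue was used. Each mouse gave 1 array of 35556 probe sets with a median log2 signal between 7.63 and 7.69, and the number of arrays limits the precision. The comparison asks how the duodenum of folate-deprived heterozygotes differed from that of folate-replete wild-type mice. Diet and genotype changed together, so their effects cannot be separated. The level of Mthfr is not analysed here.

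Among single genes, 3 fell and 1 rose in the low folate heterozygotes. Slc1a3, a glutamate transporter of the plasma membrane (probe set 10427590, chromosome 15), fell by 1.01 on the log2 scale (SE 0.11), from 9.05 ± 0.21 to 8.04 ± 0.15 (SD, n = 4 each; limma adjusted p = 0.0293). Sfi1, a centrosomal protein that binds centrin (probe set 10383632, chromosome 11), fell by 0.69 (SE 0.078), from 10.22 ± 0.13 to 9.54 ± 0.10 (limma adjusted p = 0.0293). Tnfrsf23, a decoy receptor for the death ligand TRAIL (probe set 10569504, chromosome 7), fell from 8.63 ± 0.13 to 7.98 ± 0.094, a difference of -0.65 (SE 0.077; limma adjusted p = 0.0373). The gene that rose was A530064D06Rik (probe set 10451646, chromosome 17), a predicted gene that the rule for named genes passed over and that is named after its values were seen. It went from 7.42 ± 0.042 to 8.0 ± 0.037, a difference of 0.58 (SE 0.048; limma adjusted p = 0.00642). For all 4 genes, every array of 1 group lay above every array of the other.

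**Figure D1:**
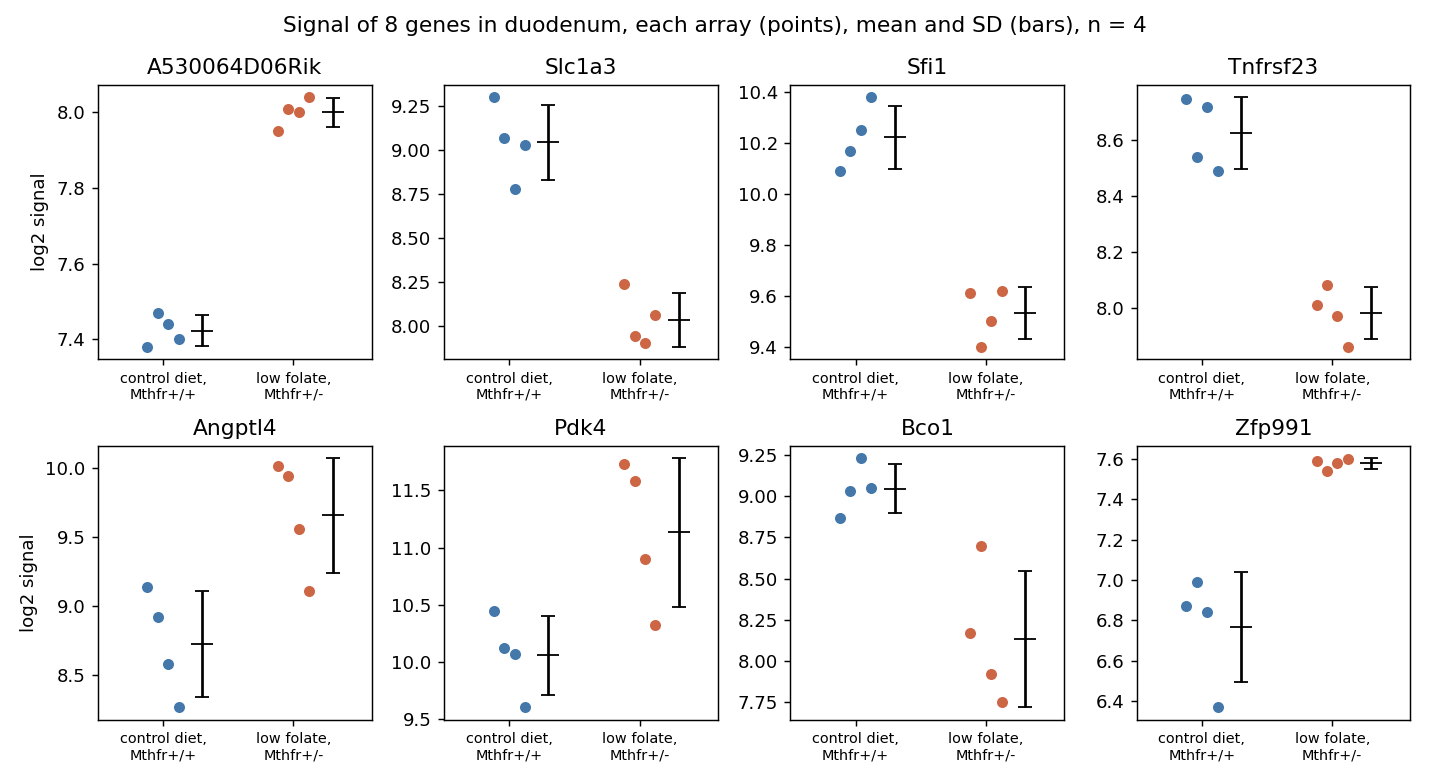
Log2 signal on each of the 8 arrays (points, 4 per group) with the group mean and SD (bars) for A530064D06Rik, Slc1a3, Sfi1, Tnfrsf23, Angptl4, Pdk4, Bco1 and Zfp991. The 4 values of Slc1a3, Sfi1 and Tnfrsf23 in the low folate heterozygotes all lie below the 4 control values, and those of A530064D06Rik all lie above.

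The genes that the rule named next, by p, did not pass (limma adjusted p from 0.115 to 0.220), and their groups did not overlap. On the higher side stood Plscr2, a phospholipid scramblase, with a log2 difference of 1.06, Zfp991, a zinc finger protein, with 0.81, and Mir192, a microRNA abundant in the intestine, with 0.68. Serpinb5, the epithelial serpin maspin, had 0.66, Scgb3a1, a secretoglobin, 0.44, BC016579 0.42 and Nmur2, a receptor for neuromedin U, 0.42. Lrrc1 had 0.41, Rps19-ps3 0.40, Ovol1, an epithelial transcription factor, 0.37, Sh2d1b1, an adaptor of natural killer cells, 0.35, and Slc9a9, an endosomal sodium/proton exchanger, 0.31. On the lower side, Gpr157 had -0.91, Bco1, which cleaves beta-carotene to retinal, -0.91, Them7 -0.79 and Dusp8, a phosphatase of MAP kinases, -0.38. Trim63, a ubiquitin ligase best known from muscle, had -0.35, Steap4, a metalloreductase, -0.32, the beta-defensin gene Defb46 -0.30, Cryaa -0.29 and Dmrt1 -0.26.

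Of the 14953 genes tested, 4 passed and 2090 had an unadjusted limma p under 0.05, where 748 would by chance; 1191 of these were higher and 899 lower in the low folate heterozygotes. The groups did not overlap for 1166 genes, or 7.8%, against 2.86% by chance. With the replicate number as a block, 2 genes passed, Slc1a3 and Angptl4, an inhibitor of lipoprotein lipase, each with a limma adjusted p of 0.00952, and Angptl4 then had a log2 difference of 0.93 (SE 0.057). Limma called 1 gene without control array 1, 20 without control array 2, 2 without low folate array 2 and 0 without low folate array 3 or 4, where 1535 and 1778 genes had an unadjusted p under 0.05. It also called 0 with the level of pancreatic genes as a covariate (1731 at unadjusted p under 0.05) and 0 without both arrays numbered 4 (1360), while an ordinary t statistic called 1 and array weights 8. With the covariate, the differences were -0.98 (SE 0.13) for Slc1a3, -0.71 (SE 0.09) for Sfi1, -0.68 (SE 0.087) for Tnfrsf23 and 0.58 (SE 0.058) for A530064D06Rik. Without both arrays numbered 4 they were -1.02 (SE 0.14), -0.66 (SE 0.077), -0.65 (SE 0.076) and 0.56 (SE 0.058).

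Of the gene lists fixed for this tissue, 7 passed by camera on the higher side, among them lists of fat use, detoxification, hormone cells and iron. Of 20 tested genes of PPAR-alpha signalling and fatty acid oxidation, 19 were higher, with a median log2 difference of 0.27 (camera adjusted p = 5.0e-06; p = 0.128 with an estimated correlation). Pdk4, the kinase that turns off pyruvate dehydrogenase, had 1.08 (SE 0.29), Angptl4 0.93 (SE 0.23), and the acyl-CoA thioesterases Acot1 and Acot2 0.87 and 0.60. Enzymes of the oxidation itself differed less, from 0.076 for Acadm to 0.46 for Acaa1b, with Hadha at 0.11 and Acadl at 0.28. Pdk4 and Angptl4 passed when adjusted over the list alone (limma adjusted p = 0.0463 each), and 0 members passed over all genes, where 9 had an unadjusted limma p under 0.05. Control array 4 had the lowest level of this list, 10.32 against 10.81 to 10.98 in the other controls, and without it the median was 0.16. Antioxidant and xenobiotic metabolism had 24 of 28 genes higher and a median of 0.31 (camera adjusted p = 1.7e-04; p = 0.105 with an estimated correlation). Its named members were Gclc, which carries out the first step of glutathione synthesis, at 0.74, and the glutathione transferases Gsta3 at 0.73, Gsta4 at 0.30 and Gstm3 at 0.20, and 0 of its members passed adjusted over the list alone or over all genes, with 8 at an unadjusted limma p under 0.05. Lower members of this list were Gpx2 (-0.165), Cyp2c55 (-0.136), Gstp1 (-0.134) and Srxn1 (-0.028). The antioxidant members Nfe2l2, Hmox1 and Txnrd1 had 0, 0.087 and 0.099, against 0.71 for Ugt2b5 and 0.67 for Ces2a. Control array 4 was lowest here too, and without it the median was 0.19.

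Enteroendocrine genes, of the hormone-making cells of the gut, were higher in 18 of 19, with a median of 0.14 (camera adjusted p = 1.7e-04; p = 0.084 with an estimated correlation). Of its members 0 passed by limma over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05. Tph1, which starts serotonin synthesis, had 0.43, Rfx6 0.38, Neurog3, the transcription factor that starts this cell fate, 0.31 and Sst, somatostatin, 0.16, and without control array 1 the median was 0.21. Iron absorption had 9 of 12 genes higher and a median of 0.17 (camera adjusted p = 0.0195; p = 0.0707 with an estimated correlation). Heph, the ferroxidase of iron export, had 0.24 (SE 0.052), Epas1, the hypoxia-responsive factor HIF-2alpha, 0.25 (SE 0.059), Ireb2, an iron-sensing regulator of mRNAs, 0.43 (SE 0.10) and Trf, transferrin, 0.29. Against the 9 higher genes, Tfrc (-0.255), Slc11a2 (-0.212) and Aco1 (-0.003) were lower, so the list did not move as a whole. Heph, Ireb2 and Epas1 passed adjusted over the list alone (limma adjusted p = 0.00784 each), and 0 did over all genes, where 4 had an unadjusted p under 0.05. The iron list did not pass without low folate array 4 (camera adjusted p = 0.0707), without both arrays numbered 4 (0.0531) or with genes under the 50th percentile left out (0.054), in a range from 0.0045 to 0.752 over its alternatives, and its median was 0.108 with no filter.

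Lists of T and intraepithelial lymphocytes, of macrophages and dendritic cells and of endothelium also passed on the higher side, while those of B and plasma cells (camera adjusted p = 0.976) and the interferon response (0.184) did not pass. The T and intraepithelial lymphocyte list had 17 of 20 genes higher and a median of 0.13 (camera adjusted p = 0.00198; p = 0.118 with an estimated correlation). Klrd1, a subunit of natural killer receptors, had 0.57 (SE 0.14) and Cd7 0.28 (SE 0.058), and both passed adjusted over the list alone (limma adjusted p = 0.0191 and 0.0138), while 0 members passed over all genes and 6 had an unadjusted p under 0.05. With genes under the 50th percentile left out the list did not pass (camera adjusted p = 0.0625, in a range from 1.1e-04 to 0.752 over its alternatives). Cd160 had 0.26 and Itgae, the integrin that holds lymphocytes in the epithelium, 0.19. The members that were lower were the T cell genes Cd2 (-0.22), Cd3g (-0.20) and Cd3e (-0.036). Cd247 (0.018) and Thy1 (0.007) hardly differed, while Cd8a had 0.19 and Cd4 0.12. Macrophage and dendritic cell genes had 15 of 17 higher and a median of 0.14 (camera adjusted p = 8.8e-04; p = 0.0903 with an estimated correlation), with Xcr1 at 0.31, Adgre1 at 0.25, Cd68 at 0.23 and Fcgr3 at 0.20. Of its members 0 passed by limma over all genes or adjusted over the list alone, against 6 at an unadjusted p under 0.05, and the median was 0.091 without control array 1. Endothelium had 12 of 14 higher and a median of 0.084 (camera adjusted p = 0.0202; p = 0.158 with an estimated correlation). Emcn had 0.27 (SE 0.062) and Kdr, the main receptor for VEGF, 0.24 (SE 0.064), and they passed adjusted over the list alone (limma adjusted p = 0.0213 and 0.0308), while Egfl7 had 0.15 and Pecam1 0.13. Over all genes 0 members passed by limma, and 4 had an unadjusted p under 0.05. The endothelium list did not pass without control array 1 (camera adjusted p = 0.058), low folate array 1 (0.0801) or low folate array 2 (0.0546), in a range from 0.00128 to 0.771 over its alternatives. Nor did it with array weights (0.0719), quantile normalization (0.06, median 0.058) or genes under the 50th percentile left out (0.0629), and its median was 0.13 without low folate array 4.

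The 7 lists that passed by camera on the lower side held cholesterol synthesis, muscle, matrix, heat shock, ribosomal, Paneth and pancreatic genes. Cholesterol synthesis had 15 of 18 genes lower and a median of -0.12 (camera adjusted p = 3.4e-04; p = 0.137 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, had -0.30 (SE 0.078) and Mvd -0.29 (SE 0.079), which passed adjusted over the list alone (limma adjusted p = 0.0397 each), and Insig1, a sterol-responsive regulator, had -0.35 and Msmo1 -0.22. Over all genes 0 of its members passed by limma and 7 had an unadjusted p under 0.05. Heat shock genes were lower in 11 of 11, with a median of -0.27 (camera adjusted p = 8.9e-04; p = 0.23 with an estimated correlation). The heat shock list was fixed as a technical check of labels and handling, not as a pathway. Hspa1a had -1.56 (SE 0.73), Hsph1 -0.97, Bag3 -0.32 and Dnaja1 -0.28. On single arrays Hspa1a ran from 8.58 to 12.32 in the controls and from 8.44 to 10.52 in the low folate group. The difference of Hspa1a ran from -2.24 to -0.78 over the alternatives. Smooth muscle genes were lower in 16 of 16, with a median of -0.22 (camera adjusted p = 7.7e-04; p = 0.313 with an estimated correlation), Cnn1 at -0.38, Actg2 at -0.36, Synm at -0.30 and Mylk at -0.23. Fibroblast and matrix genes were lower in 16 of 17, with a median of -0.12 (camera adjusted p = 0.00105; p = 0.229 with an estimated correlation), and the collagens Col1a1, Col3a1, Col4a1 and Col5a1 had -0.21, -0.20, -0.18 and -0.12. Low folate array 4 held the lowest level of smooth muscle genes, 10.04 against 10.63 to 10.68 in its group, and of fibroblast genes, 9.66 against 9.84 to 9.99. Without it the medians were -0.076 (camera adjusted p = 0.139, in a range from 1.9e-05 to 0.96 over the alternatives) and -0.084 (0.0722, in a range from 1.4e-05 to 0.824). Without control array 4 the smooth muscle median was -0.14, and without both arrays numbered 4 the heat shock median was -0.12 (camera adjusted p = 0.136, in a range from 6.0e-06 to 0.824).

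Ribosomal proteins had 17 of 23 genes lower and a median of -0.039 (camera adjusted p = 0.0219; p = 0.304 with an estimated correlation), with Rpl8 at -0.17, Rpsa at -0.16, Rpl7 at -0.14 and Rps3 at -0.11. Paneth cell genes, of the antimicrobial cells of the crypt base, were lower in 7 of 7 (median -0.11; camera adjusted p = 0.0421; p = 0.272 with an estimated correlation). Of the 18 genes fixed for the Paneth list, only 7 matched a probe set, and Defa24 (-0.112) was the only defensin among them. Itln1 had -0.46, Mmp7, which activates defensins, -0.33, Lyz1 -0.083 and Nod2 -0.082. Pancreatic acinar genes had 19 of 20 lower and a median of -1.73 (camera adjusted p = 8.9e-04; p = 0.318 with an estimated correlation). Cela1, Ctrc and Rnase1, a protease pair and a ribonuclease of pancreatic juice, had -1.53 (SE 0.89), -1.68 (SE 0.99) and -1.12 (SE 0.66), and Reg1, which intestinal epithelium also makes, 0.19. In these 3 lists and the heat shock, smooth muscle and fibroblast lists, 0 members passed by limma over all genes or adjusted over the list alone, and each list had between 0 and 3 at an unadjusted p under 0.05. The ribosomal list did not pass without control array 1 (camera adjusted p = 0.109), control array 2 (0.0522) or low folate array 3 (0.0569), nor with array weights (0.0729), quantile normalization (0.0576) or no filter (0.0661), in a range from 2.5e-04 to 0.824 over its alternatives. The Paneth list passed without control array 1 (median -0.21) or 3 (p = 0.153 and 0.293 with an estimated correlation) and did not pass without any other array (camera adjusted p from 0.0542 to 0.402), with quantile normalization (0.107) or with no filter (0.0661), in a range from 0.00212 to 0.824. Its median was -0.059 without control array 4 and -0.22 with genes under the 50th percentile left out. The pancreatic median was -2.75 without control array 3 and -1.14 without control array 4, and the list did not pass without control array 2 (-1.29, camera adjusted p = 0.0581, in a range from 2.2e-10 to 0.824).

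**Figure D2:**
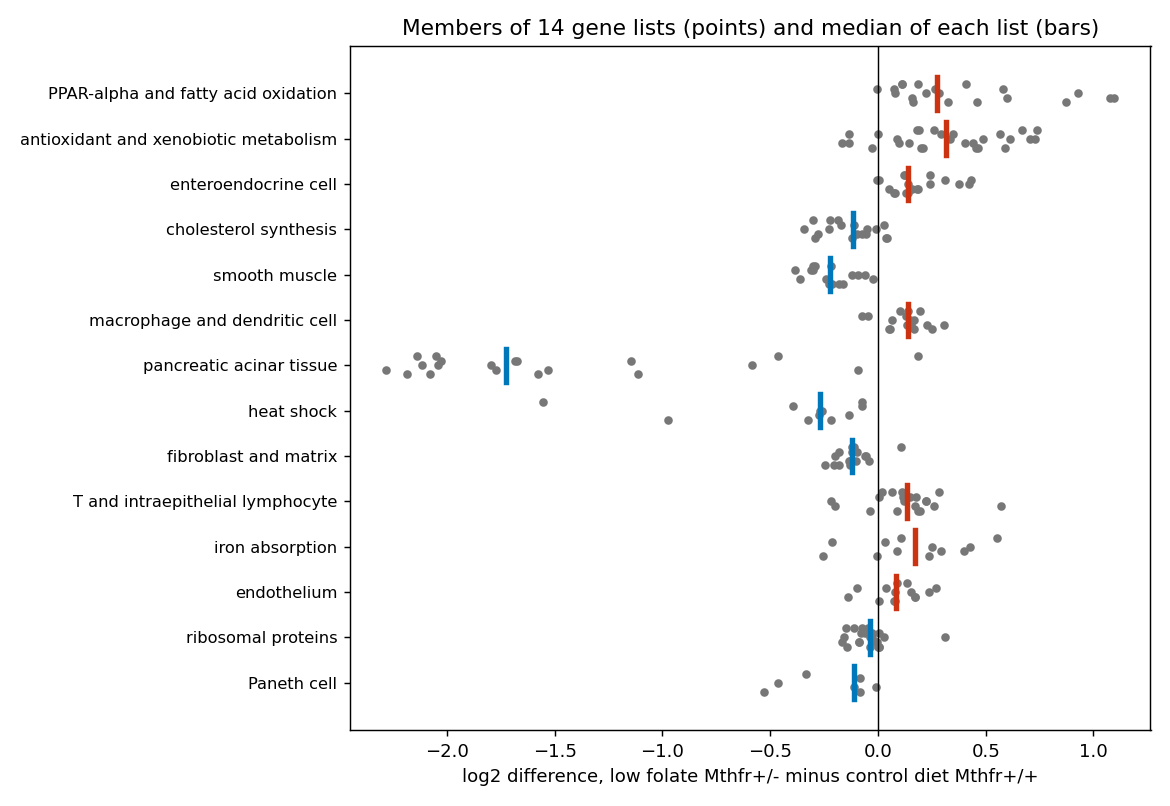
Log2 difference, low folate heterozygotes minus controls, of each tested member (points) and the median (bar) of the 14 gene lists past the camera threshold. The medians run from -1.73 for pancreatic acinar genes to 0.31 for antioxidant and xenobiotic metabolism.

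Markers of pancreas and of stomach and Brunner's glands differed between mice within both groups. The pancreatic enzyme gene Cpa1 had a log2 signal of 13.59, 14.06, 7.57 and 14.17 in control arrays 1 to 4 and 7.68, 13.95, 7.17 and 12.27 in low folate arrays 1 to 4. The mean level of the pancreatic list ran from 8.58 to 12.99 in the controls and from 8.47 to 12.32 in the low folate group. Muc6, a mucin of stomach and Brunner's glands, was at 13.46 in control array 1 and 11.68 in low folate array 1 and between 6.86 and 7.68 in the other 6 arrays. With the pancreatic level as a covariate, the median of the fatty acid oxidation list was 0.21 and that of cholesterol synthesis -0.12. The ribosomal list had a median of -0.026 with it (camera adjusted p = 0.199) and the Paneth list -0.099 (0.183), against -0.039 and -0.11 without it. The T and intraepithelial lymphocyte list had a median of 0.20 with the covariate, against 0.13 without it.

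**Figure D3:**
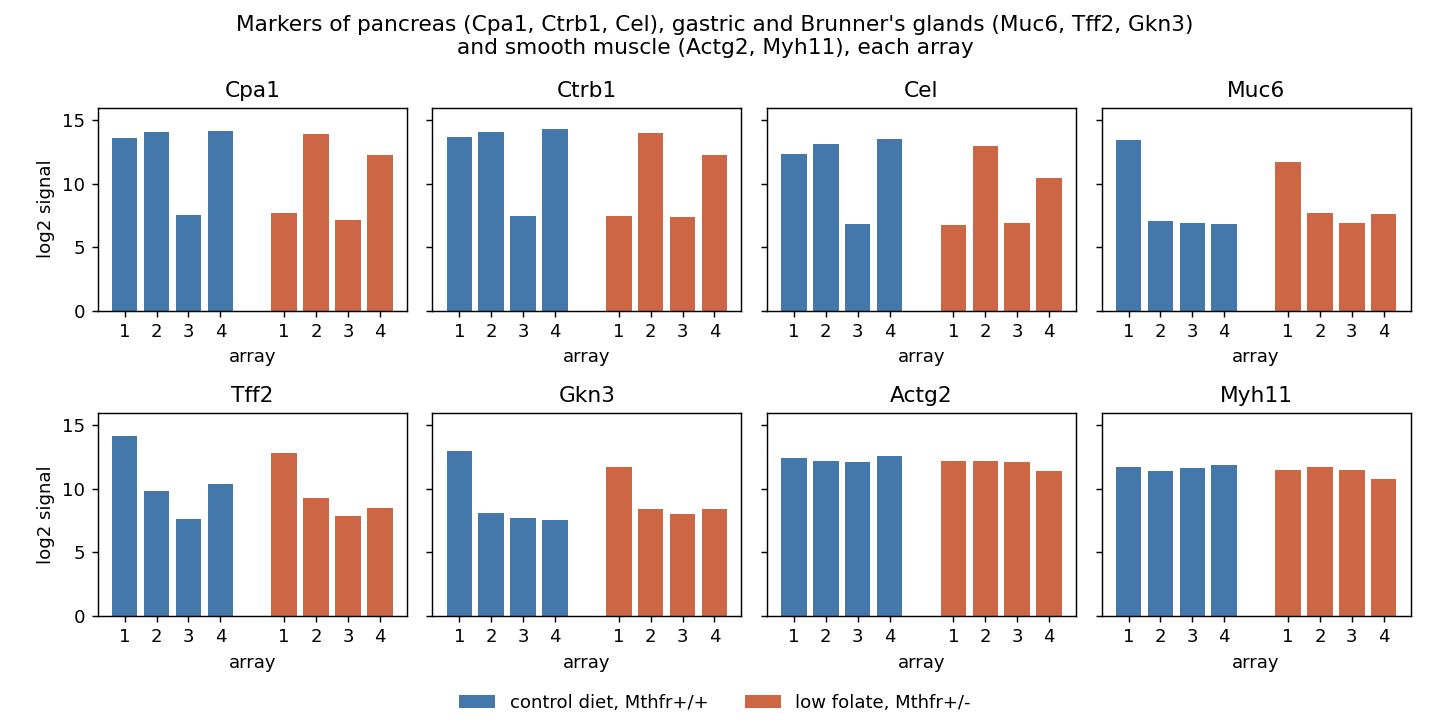
Log2 signal (bars, starting at 0) on each of the 8 arrays for the pancreatic genes Cpa1, Ctrb1 and Cel, the gastric and Brunner's gland genes Muc6, Tff2 and Gkn3, and the smooth muscle genes Actg2 and Myh11. Cpa1 lies above 12 on 3 control and 2 low folate arrays and Muc6 above 11 on 1 array of each group.

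The methionine cycle and choline list did not pass by camera (adjusted p = 0.976), but it passed by fry for change in either direction (adjusted p = 0.0314). Fry does not compare a list with other genes. Of all 14953 genes, 2090 had an unadjusted limma p under 0.05, so this pass does not set the list apart. The 6 lists named whatever their result did not pass by camera. Folate metabolism had 13 of 22 genes higher and a median of 0.038 (camera adjusted p = 0.882), with Mthfd1l, a mitochondrial enzyme of formate production, at 0.29, Slc46a1, the proton-coupled folate transporter of the duodenum, at 0.23 (13.03 ± 0.097 to 13.26 ± 0.093), Ftcd at -0.28 and Gldc at -0.12. Nucleotide synthesis had 18 of 27 genes higher and a median of 0.042 (camera adjusted p = 0.332), with Tk2 at 0.19, Rrm2 at 0.19, Tk1 at 0.18 and Prps1 at 0.18. The other probe set of Tk1 had 0.056. The p53 target genes had 13 of 20 higher and a median of 0.061 (camera adjusted p = 0.399). Tnfrsf10b, a death receptor for TRAIL, had 0.35 and passed adjusted over the list alone (limma adjusted p = 0.029), and Plk2 had 0.29, Fas 0.29 and Phlda3 -0.19. The G2/M list had 18 of 25 genes higher and a median of 0.044 (camera adjusted p = 0.189), with Ttk at 0.23, Aurkb and Bub1 at 0.17 and Mki67 at -0.12. Wnt target genes had 12 of 19 lower and a median of -0.096 (camera adjusted p = 0.139), with Rnf43 at 0.40, Wif1 at -0.19, Ccnd1 at -0.18 and Axin2 at -0.16. The DNA methylation machinery had 8 of 14 genes higher and a median of 0.013 (camera adjusted p = 0.503), with Tet1 at 0.20, Tet2 at 0.16, Uhrf2 at 0.11 and Mbd1 at 0.085. Tnfrsf10b was the 1 member of these 6 lists that passed by limma adjusted over the list alone. With 1 array left out, the median ran from 0.012 to 0.12 for p53 targets, from 0.010 to 0.081 for G2/M and from -0.15 to -0.036 for Wnt targets, which were lowest in size without control arrays 4, 4 and 1. For DNA methylation it ran from -0.002 without control array 4 to 0.030 without control array 2, and it was -0.006 with quantile normalization. Over the list, the median of folate metabolism was -0.024 without control array 3 and -0.005 without low folate array 1. Without control array 1 the nucleotide and G2/M lists passed (camera adjusted p = 0.0319 and 0.0218, in ranges up to 0.999 and 0.906 over the alternatives), and without control array 3 the Wnt list did (0.0393, in a range up to 0.824) and the nucleotide median was -0.024. With an estimated correlation these 3 calls were lost (p = 0.262 for nucleotide synthesis, 0.386 for G2/M and 0.116 for Wnt targets).

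Markers of the main epithelial cells did not pass either: brush border genes had a median of 0.017 (camera adjusted p = 0.676), goblet cell genes -0.053 (0.668), tuft cell genes 0.026 (0.843) and stem cell genes -0.11 (0.222). Across the 44 lists tested, 14 passed by camera, 7 higher and 7 lower. With an estimated correlation 0 passed (0 also at unadjusted p under 0.05, the lowest p being 0.0707). Fry called 0 lists moving 1 way (6 at unadjusted p under 0.05) and 7 changing in either direction. Those 7 were endothelium and genes flanking Mthfr (fry adjusted p = 0.016 each), iron absorption (0.0201) and apoptosis (0.0308). The methionine cycle and choline (0.0314), macrophages and dendritic cells (0.0341) and adipocytes (0.0482) completed them. As fry leaves out the other genes, these 7 lists need not differ more than other genes do. In the exact permutation test of list scores 0 passed after adjustment, and 1 list, proximal intestine, reached the smallest p possible, 0.0286.

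On the first principal component, which held 35.9% of the variance of the tested genes, the controls had scores of -8.4 ± 14.1 and the low folate heterozygotes 8.4 ± 7.7 (SD, n = 4 each), a difference of 16.8 (exact two-sided permutation p = 0.0857). Within the numbered pairs the low folate array was higher by 22.4, 5.9, 7.3 and 31.7 (exact p = 0.125 over the 16 exchanges within pairs, the smallest possible). Control array 4 had the lowest score, -26, and without it the difference was 6.4 (exact permutation p = 0.543). Without control array 3 it was 22.7, and with genes scaled to unit variance 91.7, each with the smallest exact permutation p of 0.0286. Scores on the first component also ran with the pancreatic list. Low folate arrays 1, 3 and 4 and control array 3 had the highest scores (13.3, 15.9, 5.7 and 8.5). They also had the lowest mean levels of that list (8.56, 8.47, 10.43 and 8.58). The other arrays had scores from -26 to -1.2 and levels from 11.7 to 12.99. The component therefore cannot be read as a group difference alone. The second component held 19.5%. The median SD over genes was 0.107 in the controls and 0.084 in the low folate heterozygotes, a log2 ratio of variances of -0.72 (exact two-sided permutation p = 0.0571), with values from -1.24 to -0.27 when 1 array was left out.

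Genes next to Mthfr on chromosome 4 were examined because an allele made in another strain can carry neighbouring DNA of that strain. Within 5 Mb, 7 of 80 tested genes (8.8%) had an unadjusted limma p under 0.01, against 549 of the 14873 others (Fisher's exact test, two-sided, odds ratio 2.5, 95% interval 0.97 to 5.45, p = 0.0291). At p under 0.05 it was 22 of 80 (27.5%) against 13.9% of the others (odds ratio 2.35, interval 1.37 to 3.91, exact p = 0.00167), the lowest p of the 6 pairs of window and threshold computed. The 7 genes at p under 0.01 were Zfp991 at 0.81, Rps19-ps3 at 0.40, H6pd at 0.29, Tnfrsf1b at 0.26, Clcn6 at 0.23, Gm572 at -0.19 and Gpr157 at -0.91. Of these 7, 0 passed by limma over all genes. Within 10 Mb, the window fixed beforehand, the count was 9 of 210 (4.3%) against 3.7% of the others (odds ratio 1.16, interval 0.52 to 2.27, exact p = 0.582), and within 20 Mb the odds ratio was 1.09 (exact p = 0.678). At p under 0.05 these 2 windows had odds ratios of 1.07 each (exact p = 0.763 and 0.65). Without control array 2 the odds ratio within 10 Mb was 0.93. A list of genes flanking Mthfr was also fixed beforehand. Of its 42 tested genes, 14 had an unadjusted limma p under 0.05, 8 higher and 6 lower. That list did not pass by camera (adjusted p = 0.74) and passed by fry for change in either direction (adjusted p = 0.016). The latter test does not compare the list with other genes.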

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

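The tests of the Kcnma1 gene as a whole and of pancreatic tissue, the parts that go with control array 4 and with pancreatic tissue, the pancreatic covariate and the counts over other splits of the arrays were chosen only after the result was seen. Each sample value below stood apart from the other 3 of its group: its gap to the nearest of them, divided by the range of the group, exceeded Dixon's critical value for 4 samples. Chance alone marks about 1 in 20 groups. Of 208 gene groups tested, 8 were marked where 10 were expected by chance, and of 88 groups of list scores 6 were marked where 4 were expected. A further 5 belong to genes looked at after their values were seen.

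In the low folate group, array 1 stood apart for Gclc (11.12 against 12.24 to 12.32, ratio 0.933), Xcr1 (8.85 against 9.14 to 9.17, ratio 0.901) and Mbd1 (10.05 against 10.11 to 10.12, ratio 0.853). Its list scores did so for the circadian clock (-0.85 against 0.31 to 0.47, ratio 0.879) and heat shock (0.65 against -0.89 to -0.69, ratio 0.869). Epas1 was lower in low folate array 2 (11.80 against 11.87, ratio 0.975). Low folate array 4 was lower for Mylk (10.70 against 10.93 to 10.94, ratio 0.959), Actg2 (11.40 against 12.16 to 12.17, ratio 0.979), Cnn1 (10.56 against 11.36 to 11.48, ratio 0.861), Phlda3 (8.03 against 8.20 to 8.24, ratio 0.837) and the smooth muscle score (-2 against 0.06 to 0.25, ratio 0.919). The mast cell and eosinophil score was higher in low folate array 3 (0.50 against -0.18 to -0.15, ratio 0.962).

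Among the controls, the cholesterol synthesis score was higher in array 2 (1.20 against 0.05 to 0.19, ratio 0.878) and the tuft cell score in array 4 (1.49 against -0.72 to -0.51, ratio 0.903). Control array 3 was lower for Cpa1 (7.57 against 13.59 to 14.17, ratio 0.912), Ctrb1 (7.49 against 13.71 to 14.30, ratio 0.914) and Kcnma1 (6.81 against 11.73 to 12.59, ratio 0.852). Muc6 was higher in control array 1 (13.46 against 6.86 to 7.03, ratio 0.975) and in low folate array 1 (11.68 against 6.87 to 7.68, ratio 0.83).

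A probe set of Kcnma1, a large-conductance potassium channel (probe set 10582545), read 12.59, 11.73, 6.81 and 12 in the controls and 7.31, 6.53, 6.78 and 6.86 in the low folate heterozygotes, a difference of -3.92 (SE 1.06; limma adjusted p = 0.248). The level of the whole gene is argued against by its other probe set, with a difference of -0.042. Pancreatic tissue is argued against as well: the 2 low folate arrays with Cpa1 above 12 reached at most 6.86 (of the 20 list members, 5 exceeded 10 also on the 3 arrays with Cpa1 below 8, and 0 are in another list). A wrong label on control array 3 is argued against by all genes at p under 0.01 without it, of which 31.3% placed it nearer to the low folate mean. The name of this probe set rests on the platform annotation, and where its probes lie in the genome was not checked. A transcript or a DNA variant seen by this probe set alone may differ between the mice, and diet or genotype stays open too, as untested.

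By camera with the preset correlation, the fatty acid oxidation list (19 of 20 genes higher, camera adjusted p = 5.0e-06) and the cholesterol synthesis list (15 of 18 lower, 3.4e-04) passed. With an estimated correlation they did not (p = 0.128 and 0.137). The mean levels of the lists differed by 0.40 and -0.135 between groups. Control array 4 as the whole cause is argued against: its distance from the other controls made up 0.14 of the 0.40 (35%, 95% interval 0.031 to 0.249) and 0.011 in the opposite direction for cholesterol synthesis (-0.10 to 0.121). Without it the medians were 0.16 and -0.152, or 58.2% and 132.6% of their values, and both lists passed with the preset correlation (camera adjusted p = 1.1e-04 each) and not with an estimated one (p = 0.0686 and 0.138). That array holds part of the size of the first. Pancreatic tissue as the whole cause is argued against in the same way, with parts of 0.034 (-0.163 to 0.231) and 0.004 (-0.07 to 0.078), and medians of 0.211 and -0.118 with the covariate. This test was chosen after another, of what was left, whose interval lay above 0 for fatty acid oxidation without control array 4 (0.061 to 0.458). That interval included 0 for cholesterol synthesis without the array (-0.316 to 0.025) or with all arrays (-0.274 to 0.005), and for both lists with the covariate (-0.104 to 0.836 and -0.315 to 0.038). The time since the last meal could also move both lists and cannot be told apart from the groups here, because 12 genes of fat synthesis had a median of -0.059 with 8 lower and 4 higher (exact permutation p = 0.314 for their score). Fasn had -0.34 and Acly -0.22, Srebf1 had 0.37 and Me1 0.25, and an effect of diet or genotype is untested against these.

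Control array 2 and low folate array 1 lay nearer to the other group for many genes. Of the genes at p under 0.01 when an array was left out, 67.7% placed control array 2 and 52.3% low folate array 1 nearer to the other group's mean; for control array 1 the share was 54%, and for the other arrays it ran from 19.1% to 43.3%. With the labels of the 2 arrays exchanged this could arise, so the 20 genes within 5 Mb of Mthfr at p under 0.05 without both arrays were used, since they lie beside the allele. Of the values of both arrays at these genes, 40% were nearer to the other group, between the 25% and 50% set as bounds. Over all 776 genes at p under 0.01 without both arrays the share was 54.4% (496 genes for control array 2 and 348 for low folate array 1), for which no bound was set. Single genes beside Mthfr went both ways. In control array 2 and low folate array 1, Zfp991 (6.99 and 7.59), Rps19-ps3 (7.79 and 8.24) and Clcn6 (8.22 and 8.35) kept to the labelled groups. Others, such as Spsb1 (10.09 and 10.31) and Srm (10.3 and 10.5), set both arrays nearer to the other group. An exchange and ordinary variation between mice cannot be told apart from these shares. The diet and genotype of the 2 mice are taken from the labels throughout.

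Other splits of the 8 arrays did not exclude chance for the counts of genes and lists over the whole genome. As many genes past the threshold as the real 4 came in 2 of the 35 splits, the real one included, and the highest other count was 18, in a split that set the 4 arrays with most pancreatic RNA against the rest; 13 of those 18 genes are in the pancreatic list, which points to that structure of the samples. For genes at unadjusted p under 0.01, 2 of the 35 splits reached the real 556, and the highest other count, 567, came from exchanging control array 2 and low folate array 1. As many lists as the real 14 came in 18 of the 35 splits, with up to 20. Among the 8 splits that part all 4 numbered pairs, the real one had the most genes, 4 against 0 in the others (limma) and 556 against at most 184 at p under 0.01, while 5 of the 8 had as many lists.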

How the results depend on the processing

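The pancreatic covariate, the removal of both arrays numbered 4 and the exchange within numbered pairs were chosen only after the data were seen. The 4 genes past the threshold became 1 with an ordinary t statistic (1799 genes at unadjusted p under 0.05) and 8 with array weights, of which 4 are shared. They became 2 with the replicate block, 0 with the pancreatic covariate and 0 without both arrays numbered 4, where the difference of Slc1a3 was -1.01, -0.98 and -1.02. Leaving out 1 array gave 0 to 20. With the filters, normalizations, probe sets, thresholds, pseudocount and variance trend tried, 3 or 4 genes passed. Limma's adjusted p ran from 0.00317 to 0.0782 for A530064D06Rik (past in 15 of 20 settings), from 0.00952 to 0.335 for Slc1a3 (13 of 21) and from 0.0128 to 0.335 for Sfi1 and Tnfrsf23 (10 of 21 each). With the block it was 0.0673 for A530064D06Rik and 0.0772 for Sfi1 and Tnfrsf23. The 14 lists by camera became 0 with an estimated correlation. Fry gave 0, and so did the exact permutation of scores, which cannot pass here. Both tests leave out the other genes and so do not repeat camera's question. Without both arrays numbered 4, camera called 9 lists. Without those 2 arrays smooth muscle was at -0.017 (camera adjusted p = 0.96) and fibroblast and matrix at -0.031 (0.532). The Paneth list was at -0.074 (0.532) and the ribosomal list at -0.045 (0.0668). The G2/M median turned to -0.011 there, and that of folate metabolism lay between -0.024 and 0.074 when 1 array was left out. The difference on the first principal component was 91.7 with scaled genes and 6.4 to 22.7 when 1 array was left out. The odds ratio near Mthfr was 2.5 within 5 Mb and 0.93 to 1.61 within 10 Mb when 1 array was left out. The replicate block added Angptl4 and, as a 15th list, MHC class II presentation (camera adjusted p = 0.0499, and unadjusted p = 0.341 with an estimated correlation). It changed no other call than these and the genes above. For single named genes, 2029 values kept direction and side of the threshold, 35 lost and 13 gained a call and 0 turned direction. For named lists the counts were 337, 77, 3 and 3, by the direction of the test. Among the 337, 5 medians lay on the other side of 0: nucleotide synthesis at -0.024, and DNA methylation at -0.006, -0.001, -0.002 and -0.004. The alternatives for the level of Mthfr gave no value. With fewer arrays a loss of calls follows in part from the smaller sample, and otherwise the cause was not tested. Dim genes are limited by a signal near that of the 25th percentile, 6.81.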

Other observations

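The genes of the first paragraph and the counts over other splits of the arrays were chosen only after the result was seen, and the test of windows of neighbouring genes before it. These genes are among the 1166 (7.8%, against 2.86% by chance) whose groups did not overlap; they did not pass (limma adjusted p from 0.220 to 0.251), and no list of them was tested. Hsd3b2 and Hsd3b3, steroid dehydrogenases, had log2 differences of 1.14 (SE 0.31) and 1.00 (SE 0.28), and Cyp4b1, a cytochrome P450, 0.93 (SE 0.22). Kmo and Kynu, neighbouring steps of tryptophan breakdown through kynurenine, had 0.47 (SE 0.097) and 0.26 (SE 0.054). C3ar1, a receptor for a complement fragment, had 0.52 (SE 0.10), and the myeloid lectins Clec4a3 and Clec12a had 0.37 (SE 0.072) and 0.28 (SE 0.058). Tdpoz3 had 1.75 (SE 0.36), and its control values ran from 5.15 to 6.97.

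Other lists did not pass by camera. Proximal intestine genes were higher in 13 of 15 with a median of 0.085 (camera adjusted p = 0.11). Genes of MHC class II presentation were lower in 8 of 9 with a median of -0.14 (0.11). With the replicate block that list passed (camera adjusted p = 0.0499; p = 0.341 with an estimated correlation). Enteric neurons and glia had a median of -0.094 (0.135), and the interferon response 0.10 (0.184). Adipocyte genes had a median of -0.11 and a mean of -0.053 while the test pointed up (0.907), and 3 members passed adjusted over the list alone. Test, median and mean also differed in sign for B and plasma cells (0.027 and -0.007, test down), distal intestine (-0.084 and 0.051, test down) and the methionine cycle (-0.022 and 0.010, test up, with 2 members past adjusted over the list alone). Erythroid and sex-linked lists had too few tested genes; Xist was at 12.48 ± 0.038 and 12.51 ± 0.013, as in female tissue. Of the 12146 probe sets without a gene, 0 passed by limma among themselves (lowest adjusted p = 0.0555), with 1609 at unadjusted p under 0.05 and 468 at p under 0.01, where 121 would by chance, and 366 of the 468 were higher in the low folate heterozygotes.

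The genes beside Mthfr may differ because the allele carries DNA of another strain, as a hypothesis. Of 341 windows of 80 neighbouring genes elsewhere in the genome, 12 (3.5%) held as many genes at p under 0.01 as the 7 within 5 Mb of Mthfr, under the bound of 5% set for this. Between 5 and 20 Mb from Mthfr the share was 2.7% (8 of 292). By the odds ratio chance is not excluded: 8 of the 35 splits of the arrays gave as large a ratio within 5 Mb as the real 2.5, with 4.94 as the highest other, and 13 did within 10 Mb, with 3.82 as the highest other. The other 7 splits held 1 to 5 such genes within 5 Mb, and by that number the real split's 7 was the highest of the 35, with 6 next. Of the 34 other splits, 33 had fewer genes at p under 0.01 than the real one over all genes. Adjusted over all windows, 0 passed; the 2 with most genes overlap on chromosome 6, from C1rl to Mir680-1 and from Cd9 to Dera, with 10 of 80 each (adjusted p = 0.129), and share, among others, Clec12a, Klrd1, Gabarapl1 and Clec9a.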
